A study of Danio rerio with 6 samples.

How the data were processed

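RNA was profiled in 6 libraries of thyroid follicular cells sorted from zebrafish aged 5 months, 3 pax2a-high and 3 pax2a-low. Per the labels' protocols, tissue was dissociated enzymatically, ribosomal RNA was depleted, and libraries were sequenced on an Illumina NextSeq500. Per the series design text, cells were sorted into lysis buffer. The deposited values are whole-number read counts per gene, not normalized. Reads were aligned to GRCz11 with HISAT2 and assigned to exons with featureCounts, per the submitters' processing notes, with versions, strand setting and treatment of multiply mapped reads not given in the sources used here. The table had 32059 rows with gene names of its own, and it also held rows for EGFP and mKO2. Of the counts above 0 in a library, 67.8 to 89.0% were even, as when both mates of a read pair are counted, so counts are not independent molecules, and intervals and floors cover counting error only. Gene names were those of the table, with a separate symbol table used for list members not found by name. Near-identical copies, such as the kcnj1a and atp1a1a copies and the hsp70 genes, are uncertain where reads could be split between them.

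Groups and replicate numbers came from the sample titles. Nothing in the labels says that replicates came from separate animals or pools, so p-values measure the spread between these samples, which may be technical. Depth was 18014891 to 35403210 counts in pax2a-high and 6053741 to 10932845 in pax2a-low libraries. The floor of 3 counts was 0.085 to 0.186 CPM in pax2a-high and 0.237 to 0.586 CPM in pax2a-low libraries.

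Differential expression was computed from the counts with edgeR 4.0.16 in R 4.3.3: filterByExpr, TMM scaling, robust quasi-likelihood fits on the group alone, and Benjamini-Hochberg adjustment over the 12524 genes tested, at a threshold of 0.05. Log2 fold changes are pax2a-high minus pax2a-low, with a standard error taken from the quasi-likelihood statistic. CPM (counts per 1000000) are over the TMM-scaled library size. Folds against a group at 0 counts are bounds that set the other group's mean CPM against the floor of 3 counts per library, averaged over the group. A single library can lie below such a bound, and the bounds leave out the spread between libraries. With 1 to 3 counts in a group, the ratio of pooled rates was given with its 95% exact Poisson interval. Mitochondrial rows are the 37 rows named by the table as mitochondrial.

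Before the data were examined, the tests, the alternatives, 28 gene lists and the rule for named genes were fixed. The rule names pax2a, detected members of the thyroid lists, the 12 genes with the largest positive and the 12 with the largest negative log2 fold change among those past the threshold with a mean of at least 5 CPM, no overlap between the groups and a descriptive symbol, and up to 4 members of each other list with the smallest p. EGFP, mKO2, krt8, cldnb, cldne, cldnh, tjp1b, klf2b, hsp90aa1.2, hsp70l and hsp70.3 lie outside the rule and were chosen after their values were seen, as were the ionocyte genes of the closing section. Lists with at least 5 tested members were tested with camera (limma 3.58.1, preset correlation 0.01), again with an estimated correlation, and with fry. The thrombocyte, cardiac muscle, skeletal muscle and neuroendocrine lists had 2, 3, 3 and 4 tested members, of which 0 passed, and were not tested as lists. By fry's directional test, the cytosolic ribosomal, endoplasmic reticulum folding, signalling target, mitochondrially encoded and thyroid hormone lists had adjusted p of 0.033, 0.033, 0.033, 0.025 and 0.016, without comparison to other genes. Other lists that passed camera did not pass fry's directional test. These were nuclear oxidative phosphorylation, epithelial junctions, macrophages, extracellular matrix, and epidermis, gill and ionocytes (fry adjusted p of 0.487, 0.724, 0.126, 0.089 and 0.089).

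Alternatives were DESeq2 size factors in edgeR, library sizes without mitochondrial rows (no nuclear ribosomal RNA row is named in the table), no count filter, a filter of 5 CPM in 3 libraries, DESeq2 1.42.0, limma voom with quality weights, a replicate block, a threshold of 0.01, a minimum fold of 1.5, and leaving out each library or both libraries of a number. For DESeq2 the lists were tested on its Wald statistics with the pre-ranked form of camera. Thinning every library to the total of the shallowest, halving the counts and a list of ionocyte markers were added after the data were seen. For the depth test of the ionocyte genes, 4 decision rules were tried after its value was known. Members still lower after thinning could only go one way in the deeper libraries, a Poisson interval ignored the paired counts, and the pooled share was moved across its bound by atp1b1a alone, so the order-statistic interval of the median share over members was used, for all members and for those not seen before. The mitochondrial test was first run on TMM-scaled library sizes, where the scaling fixed its outcome, and was replaced by the same comparison on unscaled sizes with the same bound. There the unequal mitochondrial share fixed the outcome, so neither form decides the question.

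The methods were tested on simulated counts for this comparison, drawn for 12524 genes with the real means, library sizes and dispersions and 200 changed genes. Of changed genes that edgeR tested, 0 of 56 were recovered at a fold of 4, 2 of 50 at 16 and 9 of 45 at 64, among 10777 genes tested, and 2 of its 13 calls were false. DESeq2 made 252 calls of which 217 were false, and limma made 1 call, which was true. Simulated changes of 4-fold were not recovered, and a gene that did not pass is not shown to be unchanged. The simulation differs from the data, where edgeR called 323 genes and hspa5 passed at 3.61-fold. Its rates, also the false calls of DESeq2, may therefore not carry over to the data. Of 3 simulated lists, camera gave p of 6.83e-13 and 7.26e-15 for those with changed genes and 0.041 for the list with none, and 0.0017, 0.0027 and 0.125 with an estimated correlation.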

Results

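RNA was sequenced from thyroid follicular cells of zebrafish aged 5 months, the cells that line the thyroid follicles, make thyroglobulin and release thyroid hormone. The fish carried a nuclear EGFP reporter driven by the thyroglobulin promoter and an mKO2 reporter knocked in at pax2a, which encodes a paired-box transcription factor of thyroid development. Sorting on mKO2 brightness gave a pax2a-high and a pax2a-low population, each with 3 libraries. Total counts per library were 18014891, 20392697 and 35403210 in the pax2a-high replicates 1, 2 and 3 and 6053741, 7189239 and 10932845 in the pax2a-low ones. Genes with at least 1 count numbered 12333, 16200 and 19550 in the pax2a-high libraries and 8392, 14215 and 11301 in the pax2a-low libraries. The comparison asks how the transcriptomes of follicular cells with high and low pax2a reporter signal differ.

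The gene behind the sort, pax2a (ENSDARG00000028148), had 4969, 8521 and 20604 counts in the pax2a-high libraries and 12, 10 and 2014 counts in the pax2a-low ones. Its level was 443 ± 139 CPM (SD, n = 3) against 54.2 ± 90.7 CPM (SD, n = 3), with all 3 pax2a-high libraries above all 3 pax2a-low libraries. The log2 fold change of 3.03 (SE 1.75) did not pass edgeR's quasi-likelihood test (Benjamini-Hochberg adjusted p = 0.595). Without pax2a-low replicate 3, which lay far above the other pax2a-low libraries, the log2 fold change was 7.89 (edgeR adjusted p = 7.1e-08). With the replicate block it was 6.16 (edgeR adjusted p = 1.41e-08), although the labels do not say what a replicate number marks. The mKO2 reporter had 74, 671 and 654 counts in pax2a-high and 0, 6 and 0 in pax2a-low cells (edgeR adjusted p = 0.344). The EGFP reporter was at 312 ± 90.8 CPM in pax2a-high and 83.8 ± 81.9 CPM in pax2a-low cells (SD, n = 3 each; edgeR adjusted p = 0.182), and passed without pax2a-low replicate 3 (log2 fold change 3.03, edgeR adjusted p = 0.0051). As pax2a defined the sort, its difference checks the labels and is no separate finding.

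Of the thyroid hormone genes tested, slc5a5 and dio1 rose in the pax2a-high cells. The sodium-iodide symporter slc5a5, which carries iodide into the cell, rose 35.8-fold (log2 fold change 5.16, SE 0.77, edgeR adjusted p = 0.00086), from 7.86 ± 5.78 to 280 ± 71.3 CPM (SD, n = 3 each). The deiodinase dio1, which removes iodine from thyroid hormones, rose with a log2 fold change of 6.01 (SE 1.32, edgeR adjusted p = 0.020). Thyroglobulin (tg), the hormone precursor protein, took 19.1 ± 4.48% of all counts in pax2a-high and 1.55 ± 1.95% in pax2a-low cells (SD, n = 3 each). The shares did not overlap, and a two-sided exact permutation test gave p = 0.1, the smallest that 3 libraries against 3 allow. Its log2 fold change of 3.85 (SE 0.92) missed the threshold over all genes (edgeR adjusted p = 0.118), and without pax2a-low replicate 3 it was 5.42 (edgeR adjusted p = 1.03e-11). Of the 12 tested genes of thyroid hormone handling, 2 rose and 10 did not pass, while 5 were higher when adjusted over the list alone. The list as a whole was higher (median log2 fold change 3.16, camera adjusted p = 0.0034; adjusted p = 0.312 with an estimated correlation).

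Thyroid transcription factors had positive log2 fold changes of 3.85 for hhex (SE 1.17), 3.49 for nkx2.4b (SE 1.44) and 1.98 for pax8 (SE 0.73). That of prdm1a was negative (-3.37, SE 2.44), and none of the 6 tested passed the test over all genes. Adjusted over the list alone, 2 were higher, and the list had a median log2 fold change of 2.505 (camera adjusted p = 0.111). The 6 include pax2a (3.03), which defined the sort, so the list's median and camera test are not independent of the sort. The thyrotropin receptor gene tshr was at 260 ± 80.9 CPM in pax2a-high and 18.5 ± 26.8 CPM in pax2a-low cells (SD, n = 3 each; edgeR adjusted p = 0.388). Thyroid peroxidase (tpo) was not analysed here. The call on slc5a5 held when any 1 library was left out but not with limma (adjusted p = 0.078) or without both libraries numbered 1 (0.069) or 2 (0.115), while that on dio1 was lost without pax2a-high replicate 1 (adjusted p = 0.062), pax2a-high replicate 3 (adjusted p = 0.084) or pax2a-low replicate 2 (adjusted p = 0.071), by edgeR where not named otherwise. With limma the dio1 call was also lost (limma adjusted p = 0.092).

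**Figure D1:**
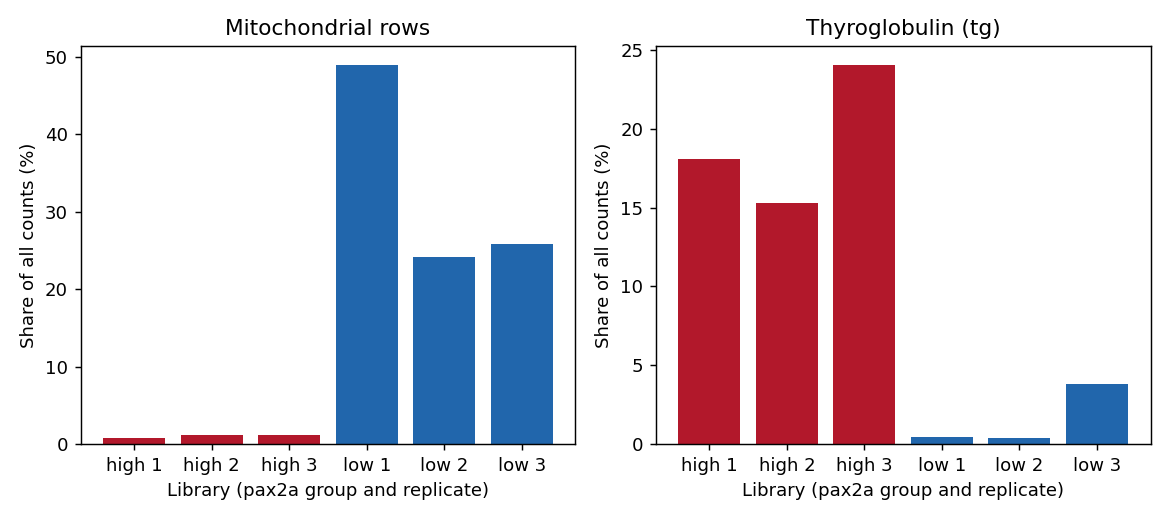
Share of all counts in each library, in percent, taken by the 37 mitochondrial rows (left) and by tg (right), with 1 bar per library, pax2a-high in red and pax2a-low in blue. Mitochondrial rows took 0.80 to 1.17% in the pax2a-high libraries and 24.1 to 49.0% in the pax2a-low libraries, and tg took 15.3 to 24.0% and 0.398 to 3.80%.

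Mitochondrially encoded genes were much lower in the pax2a-high cells. Mitochondrial rows took 1.04 ± 0.205% of counts in pax2a-high and 33.0 ± 13.9% in pax2a-low libraries (SD, n = 3 each; two-sided exact permutation p = 0.1, the smallest possible). All 13 protein-coding mitochondrial genes fell, with log2 fold changes of -6.17 for mt-atp6 (SE 0.47), -6.15 for mt-cyb (SE 0.49) and -5.45 for mt-co2 (SE 0.43), each with an edgeR adjusted p of 2.06e-06. The list's camera adjusted p was 2.98e-29, and adjusted p = 0.312 with an estimated correlation. Nuclear genes of oxidative phosphorylation were also lower as a list (median log2 fold change -0.92, camera adjusted p = 0.00029; adjusted p = 0.422 with an estimated correlation), yet 0 of 76 passed on their own. With limma the calls on mt-atp6, mt-cyb and mt-co2 were lost (limma adjusted p of 0.131, 0.168 and 0.219). At an unadjusted p under 0.05 by edgeR, 576 of all 12524 tested genes were lower and 1222 higher.

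Across all genes, 140 were higher and 183 lower in pax2a-high cells at a false discovery rate of 0.05 by edgeR. The counts rested on few libraries: without pax2a-high replicate 1 they fell to 40 higher and 120 lower, and without pax2a-high replicate 3 the higher genes numbered 246. They numbered 270 without pax2a-low replicate 1 and 247 without pax2a-low replicate 3, and the common biological coefficient of variation was 1.499.

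The genes with the largest increases were undetected in all 3 pax2a-low libraries. Their folds are bounds from counting alone and leave out the spread between libraries. For example, tshr had 0, 50 and 624 counts in the pax2a-low libraries. The small heat shock protein gene hspb8 was at 484 ± 280 CPM (SD, n = 3) in pax2a-high cells, at least 1211-fold higher than the floor of 3 counts per library (edgeR adjusted p = 2.89e-06). The chloride intracellular channel gene clic5a was at least 843-fold higher (edgeR adjusted p = 4.34e-06). Bounds were at least 323-fold for adm2a, which encodes an adrenomedullin peptide, at least 207-fold for the membrane metalloproteinase gene mmp14a and at least 183-fold for qdpra, which encodes dihydropteridine reductase. The remaining 7 of the 12 with the largest increases were large2, psmb7, ppp1r3cb, hspa8b, st3gal3b, npy8br and gabra6b, at least 105-fold to 165-fold higher. Without pax2a-high replicate 1 the calls on qdpra and on these 7 were lost (edgeR adjusted p of 0.068 for qdpra and 0.152 to 0.203 for the others), as they were without pax2a-high replicate 2 for ppp1r3cb (0.055), npy8br (0.151) and gabra6b (0.076), without pax2a-high replicate 3 for st3gal3b (0.062) and gabra6b (0.150), and without pax2a-low replicate 2 for large2, psmb7, hspa8b, st3gal3b, npy8br and gabra6b (0.067 to 0.086). The hspb8 call was lost with limma (adjusted p = 0.442) and without both libraries numbered 1 (edgeR adjusted p = 0.059), the adm2a call without both numbered 2 (0.134) and the mmp14a call without both numbered 1 (0.093) or 2 (0.184). Limma also ended the calls on large2 and psmb7 (limma adjusted p of 0.060 and 0.057).

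The genes with the largest decreases were expressed in the pax2a-low cells and almost absent from the pax2a-high cells. The beta subunit gene of the sodium-potassium pump, atp1b1b, had 8 counts over the pax2a-high and 67999 over the pax2a-low libraries (log2 fold change -14.37, SE 0.60, edgeR adjusted p = 8.79e-10). The inward-rectifier potassium channel gene kcnj1a.5 was at least 2776-fold lower, the adenylate cyclase gene adcy6b at least 2427-fold lower and the regulator of G-protein signalling rgs5b at least 1863-fold lower in pax2a-high cells (edgeR adjusted p of 2.06e-06, 2.06e-06 and 2.48e-06). The ammonium transporter gene rhbg was at least 1402-fold lower and the growth-factor-binding protein gene igfbp5a at least 980-fold lower. The other members of the 12 were pip5k1ca, foxg1c, SH3TC1, capn8, s100a11 and ponzr3, at least 737-fold to 1336-fold lower. These bounds, too, leave out the spread between libraries. Calls were lost without both libraries numbered 1 for igfbp5a, pip5k1ca, capn8 and ponzr3 (edgeR adjusted p of 0.052, 0.119, 0.097 and 0.067) and without both numbered 2 for rhbg, igfbp5a, capn8, s100a11 and ponzr3 (0.054, 0.107, 0.053, 0.159 and 0.089). Several kcnj1a copies resemble each other, and reads shared between them could be split differently, so their separate values are uncertain.

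**Figure D2:**
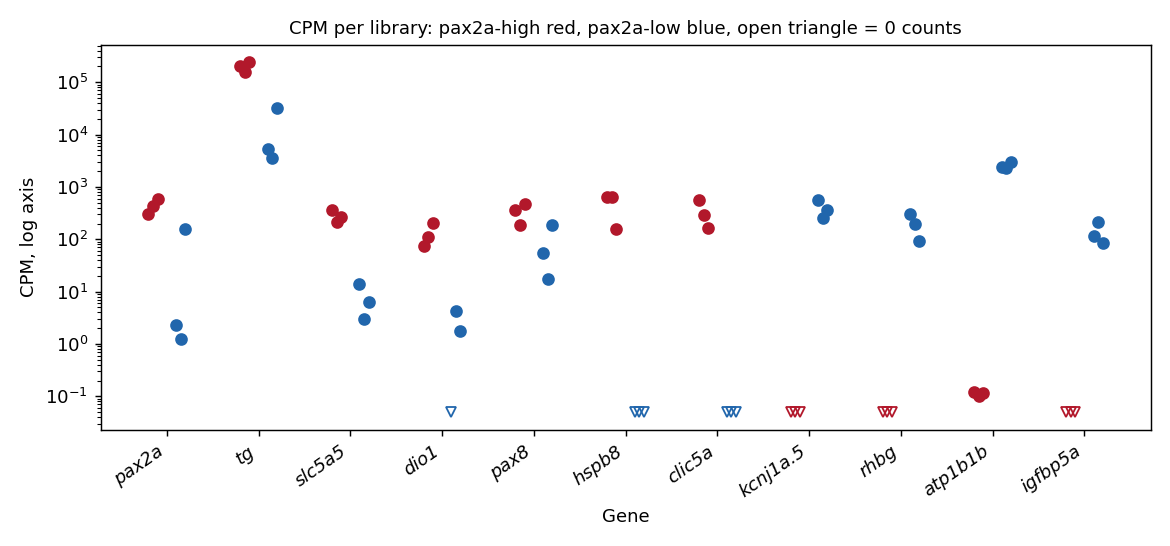
CPM over effective library sizes, on a log axis, of 11 genes in each of the 6 libraries, with 1 point per library, pax2a-high in red and pax2a-low in blue; open triangles at the bottom mark libraries with 0 counts. The pax2a level of pax2a-low replicate 3 was 159 CPM against 2.34 and 1.26 CPM in pax2a-low replicates 1 and 2, and kcnj1a.5, rhbg and igfbp5a had 0 counts in all 3 pax2a-high libraries.

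The lists of cytosolic ribosomal proteins and of endoplasmic reticulum folding were higher in pax2a-high cells by camera with the preset correlation. Cytosolic ribosomal protein genes had a median log2 fold change of 1.90, with 15 of 77 higher over all genes, 58 when adjusted over the list alone and 0 lower (camera adjusted p = 7.28e-15; adjusted p = 0.422 with an estimated correlation). Examples were rps18 (log2 fold change 2.64, SE 0.54) and rplp1 (2.38, SE 0.51), with edgeR adjusted p of 0.014 and 0.017. Endoplasmic reticulum folding genes had a median of 1.91, with 2 of 45 higher over all genes and 4 when adjusted over the list alone (camera adjusted p = 8.65e-05; adjusted p = 0.422 with an estimated correlation). Those that rose were the cyclophilin gene ppib (log2 fold change 3.94, SE 0.78, edgeR adjusted p = 0.0097) and the chaperone gene hspa5 (1.85, SE 0.45, edgeR adjusted p = 0.037). The tg share and the mitochondrial share differed between the same libraries. The hspa5 call was lost without pax2a-high replicate 1 or pax2a-low replicate 2, the ppib call without pax2a-low replicate 2, the rps18 call without either pax2a-high replicate 1 or pax2a-low replicate 2 and the rplp1 call without pax2a-high replicate 1. With DESeq2 the calls on hspa5, rps18 and rplp1 were also lost (DESeq2 adjusted p of 0.415, 0.174 and 0.240). Limma ended those on hspa5, ppib and rps18 (limma adjusted p of 0.266, 0.091 and 0.073).

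The lists of signalling targets and of extracellular matrix were also higher by camera with the preset correlation. Of 32 tested Notch, BMP, TGF-beta and Wnt target genes, 3 rose over all genes and 3 when adjusted over the list alone, with a list median of 1.73 (camera adjusted p = 0.014; adjusted p = 0.422 with an estimated correlation). They were the Notch target genes her6 (log2 fold change 3.53, SE 0.66, edgeR adjusted p = 0.0064) and her15.1 (pooled ratio 1355, 95% counting interval 375 to 11189), and the ligand gene bmp4 (pooled ratio 510, 95% counting interval 141 to 4210). In the extracellular matrix list 1 of 15 rose, both over all genes and adjusted over the list alone, the follistatin-like gene fstl1b (log2 fold change 8.62, SE 1.81, edgeR adjusted p = 0.015; list median 1.82, camera adjusted p = 0.034; adjusted p = 0.443 with an estimated correlation). The matrix list's call was lost without any 1 of 5 libraries, all but pax2a-low replicate 2, and the signalling list's without pax2a-high replicate 1. The her6 call was lost without pax2a-high replicate 1 (edgeR adjusted p = 0.052) or pax2a-low replicate 1 (0.098), the bmp4 call without pax2a-high replicate 1 (0.203), pax2a-high replicate 2 (0.296) or pax2a-low replicate 2 (0.109), the her15.1 call without both libraries numbered 1 (0.069) or 2 (0.264), and the fstl1b call without pax2a-high replicate 1 (0.097), pax2a-high replicate 3 (0.057) or pax2a-low replicate 2 (0.058). DESeq2 also ended the her6 call (DESeq2 adjusted p = 0.103), and limma the bmp4 call (limma adjusted p = 0.072).

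Epithelial junction and keratin genes went both ways. Of 35 tested, 5 rose and 4 fell over all genes, and 6 were higher and 6 lower when adjusted over the list alone. The claudin gene cldn7b (log2 fold change 2.93, SE 0.46), the keratin genes krt18a.1 (2.53, SE 0.40), krt18b (4.18, SE 0.79) and krt8 (1.66, SE 0.36), and cldnb (1.95, SE 0.46) rose. The tight junction scaffold genes tjp1a (-2.39, SE 0.44) and tjp1b (-1.81, SE 0.45), with cldne (-3.90, SE 0.95) and cldnh (-6.82, SE 1.37), fell. The list median was -0.32 (camera adjusted p = 0.034; adjusted p = 0.443 with an estimated correlation), and the camera call was lost without pax2a-high replicate 3 or pax2a-low replicate 1. Without pax2a-high replicate 1 the calls on tjp1a, tjp1b, krt8, cldnb and cldne were lost (edgeR adjusted p of 0.053, 0.203, 0.062, 0.176 and 0.117), as they were without pax2a-high replicate 2 for tjp1b (0.110), without pax2a-low replicate 1 for tjp1b, cldne and cldnh (0.059, 0.133 and 0.231), without pax2a-low replicate 2 for cldnb, cldne and cldnh (0.064, 0.195 and 0.054) and without pax2a-low replicate 3 for cldnh (0.092). The calls on cldn7b and krt18a.1 were lost with DESeq2 (adjusted p of 0.136 and 0.198), and those on cldn7b, krt18a.1 and krt18b with limma (0.570, 0.433 and 0.114), without both libraries numbered 1 (0.240, 0.164 and 0.176) and without both numbered 2 (0.123, 0.175 and 0.264). DESeq2 also ended those on tjp1a, tjp1b, krt8, cldnb and cldne (DESeq2 adjusted p of 0.161, 0.304, 0.480, 0.386 and 0.069). With limma the cldnb call was lost as well (limma adjusted p = 0.503).

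Of the lists of other cell types, 2 were lower in pax2a-high cells by camera with the preset correlation. Of 17 tested epidermis, gill and ionocyte markers, 2 fell over all genes, and 4 were lower and 1 higher when adjusted over the list alone (median log2 fold change -2.14, camera adjusted p = 5.54e-05; adjusted p = 0.312 with an estimated correlation). They were foxi3b, a forkhead factor of fish ionocytes (log2 fold change -12.62, SE 1.14, edgeR adjusted p = 4.34e-06), and the carbonic anhydrase gene ca15a (at least 696-fold lower, edgeR adjusted p = 0.00099), whose call was lost without both libraries numbered 1 (0.179) or 2 (0.209). Of 10 macrophage and dendritic markers 0 passed over all genes and 4 were lower when adjusted over the list alone (median -2.73, camera adjusted p = 0.00022; adjusted p = 0.422 with an estimated correlation). The antigen presentation gene cd74a was at 48.5 ± 41.6 CPM in pax2a-high and 577 ± 254 CPM in pax2a-low cells, and mpeg1.2 at 3.05 ± 2.91 and 97.4 ± 35.9 CPM (SD, n = 3 each), neither passing the test. None of the 10 lists that passed camera passed with an estimated correlation, among 24 lists tested.

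The stress and proteolysis lists did not pass camera, although single members did. Among 67 immediate early and dissociation stress genes, 7 rose and 1 fell over all genes, and 17 were higher and 3 lower when adjusted over the list alone (median log2 fold change 0.78, camera adjusted p = 0.084). The phosphatase gene dusp5 (3.28, SE 0.43), the antiproliferative gene btg1 (2.32, SE 0.35) and the AP-1 gene fosl1a (2.102, SE 0.39) rose, while the Krüppel-like factor gene klf2b fell (-4.06, SE 0.89). The heat shock genes hsp90aa1.2 (1.72, SE 0.37), hsp70l (1.61, SE 0.35) and hsp70.3 (1.48, SE 0.37) rose, and with hsp70.1 and hsp70.2 they took 6.29 ± 1.26% of counts in pax2a-high and 2.31 ± 1.18% in pax2a-low libraries (SD, n = 3 each). The klf2b call was lost without pax2a-high replicate 1 (edgeR adjusted p = 0.130) or pax2a-low replicate 2 (0.137), the hsp90aa1.2 call without pax2a-high replicate 1 (0.057) and the hsp70.3 call without pax2a-high replicate 1 (0.153) or pax2a-low replicate 3 (0.065). The calls on dusp5, btg1, fosl1a, hsp70l and ctsba were lost with DESeq2 (adjusted p of 0.061, 0.244, 0.313, 0.539 and 0.162), without both libraries numbered 1 (0.081, 0.128, 0.239, 0.283 and 0.125) and without both numbered 2 (0.094, 0.117, 0.092, 0.263 and 0.134), and those on btg1 and hsp70l with limma (0.352 and 0.752). DESeq2 also ended the calls on hsp90aa1.2 and hsp70.3 (DESeq2 adjusted p of 0.488 and 0.587), as did limma (limma adjusted p of 0.779 and 0.424). In the lysosome and thyroglobulin proteolysis list 2 of 44 rose, over all genes and adjusted over the list alone (median 0.19, camera adjusted p = 0.666). They were the cathepsin B gene ctsba (log2 fold change 2.65, SE 0.44, edgeR adjusted p = 0.0021) and lrp2a, the endocytic receptor megalin (2.15, SE 0.49, edgeR adjusted p = 0.026). The lrp2a call was lost without pax2a-high replicate 1 or pax2a-low replicate 2, and with DESeq2 (DESeq2 adjusted p = 0.341).

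In the remaining lists few genes passed. In the cyclic AMP and thyrotropin signalling list 2 of 30 fell, adcy6b and the mitochondrial biogenesis coactivator gene ppargc1a (log2 fold change -11.52, SE 1.48, edgeR adjusted p = 0.00091; 0.122 without both libraries numbered 1), and the same number was lower when adjusted over the list alone. This list had a positive median of 0.30 while camera pointed lower (camera adjusted p = 0.266). The same held for the neutrophil list (median 0.45, camera adjusted p = 0.719) and the leukocyte list (median 0.02, camera adjusted p = 0.154), in which gata3 fell (-4.98, SE 1.16). The antioxidant gene sesn1 (3.16, SE 0.79) and the sterol synthesis gene sqlea (9.03, SE 1.89) rose, and the interferon-induced gene ifi45 was at least 104-fold higher. Their lists had camera adjusted p of 0.111, 0.751 and 0.208. The calls on sesn1, ifi45 and gata3 were lost without any 1 pax2a-high library or pax2a-low replicate 2 (edgeR adjusted p of 0.068 to 0.159, 0.064 to 0.203 and 0.056 to 0.170), and that on sqlea without pax2a-high replicate 1 (0.113), pax2a-high replicate 2 (0.077) or pax2a-low replicate 2 (0.054). With DESeq2 and with limma the sesn1 call was also lost (DESeq2 adjusted p = 0.103, limma adjusted p = 0.159). Lists of the cell cycle (0 of 14; camera adjusted p = 0.513), vascular smooth muscle (1 of 7, rgs5b; 0.200), endothelium (0 of 11; 0.218), erythrocytes (0 of 5; 0.446), and neurons and glia (0 of 5; 0.323) did not pass.

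**Figure D3:**
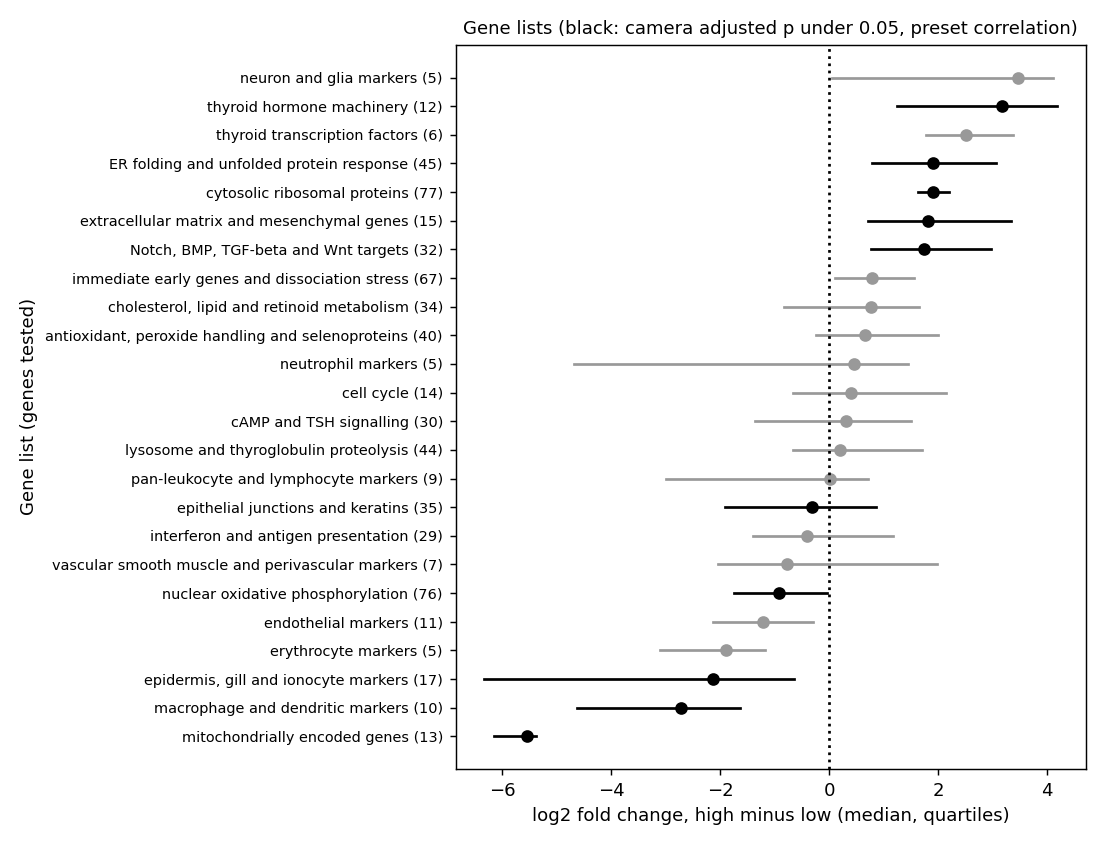
Median (points) and quartiles (lines) of the log2 fold change, pax2a-high minus pax2a-low, for each of the 24 gene lists tested, with the number of genes tested in parentheses; black marks a camera adjusted p under 0.05 with a preset correlation and grey the rest. Thyroid hormone genes had a median of 3.16, cytosolic ribosomal proteins 1.90 and mitochondrially encoded genes -5.55.

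By Pearson correlation libraries were closer within a group than between groups, while the Spearman ranges of pax2a-low libraries and of pairs between groups overlapped. Pearson correlations of log2 CPM were 0.606 to 0.732 among pax2a-high libraries, 0.463 to 0.499 among pax2a-low libraries and 0.283 to 0.392 between the groups, and Spearman correlations were 0.683 to 0.800, 0.476 to 0.542 and 0.314 to 0.487. The first principal component held 44.5% of the variance and parted the groups. These are correlations across genes, which are not independent replicates.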

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

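Thinning and halving of the counts were chosen after the data were seen. The gene counts depended on the settings: 328 higher and 299 lower with no count filter, 73 higher with the stricter filter, 961 and 500 with DESeq2 (62 and 148 shared with the main calls, and most simulated calls of DESeq2 were false), 309 lower with limma, 44 and 110 at a threshold of 0.01, and 92 higher with a minimum fold of 1.5. Leaving out libraries gave 6 to 270 higher and 42 to 253 lower genes, lowest without both libraries numbered 2 and both numbered 1. DESeq2 size factors moved the median log2 fold change of all tested genes from 0.35 to 0.24. Larger moves came with limma (1.52), the replicate block (1.42) and without pax2a-low replicate 2 (0.88). With an estimated correlation 0 lists passed in place of 10. The replicate block gave 425 higher genes and a pax2a log2 fold change of 6.16 (edgeR adjusted p = 1.41e-08), with 2.33 for EGFP (0.0115). It ended the calls on bmp4 (edgeR adjusted p = 0.082), atp1a1a.2 (0.307) and the extracellular matrix list (camera adjusted p = 0.061). Same-numbered libraries' deviations correlated at 0.038 to 0.057, under the limit for pairing, although 6 of 6 libraries correlated best with their own number, a hint from the data and not the design, and the table's columns name shared sets without saying what a set is. For pax2a, leaving out libraries gave log2 fold changes of 2.41 to 7.89. With no filter, the lowest within-group correlation fell below the highest between groups (difference -0.027 against 0.07); the cause was not tested.

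Of 71 named genes past the threshold with values in the fits, 70 passed after thinning, 71 with halved counts, 53 with the stricter filter, 47 with limma and 46 of 69 with DESeq2, and 34 were lost without some single library. Only 17 passed without both libraries numbered 1 and 18 without both numbered 2, against 54 without both numbered 3. Of 49 changes of direction, 0 passed the threshold in the alternative, and 1 of the 16 results had passed in the main fit, the extracellular matrix list. The cause was not tested. With DESeq2, camera turned for the matrix list (median -0.016, adjusted p = 0.855), thyroid transcription factors (1.82), erythrocyte markers (0.21) and lipid metabolism (0.71). With limma, log2 fold changes turned to 0.47 for thraa, 1.81 for znfl2a, 2.14 for hemgn, 0.48 for atp2a1, 1.16 for gip and 3.52 for chgb. With the replicate block they were 0.29 for thraa, 5.05 for znfl2a, 1.21 for hemgn, 1.23 for atp2a1, 0.018 for eno3, 4.15 for gfap, 0.53 for gip and 2.64 for chgb. Leaving out libraries gave -1.61 to 0.32 for thrb, -1.21 to 9.85 for chgb, -1.05 to 1.40 for thraa, -4.41 to 8.48 for znfl2a, -2.34 to 2.85 for atp2a1, -0.84 to 0.19 for eno3, -3.41 to 7.58 for gfap, -2.81 to 8.46 for hemgn and -1.67 to 3.26 for gip. List medians ranged from -0.10 to 1.25 for lysosome and proteolysis, -2.62 to 8.46 for erythrocyte markers, -0.24 to 2.72 for lipid metabolism and -0.59 to 2.75 for the cell cycle. Counting each gene or list once per alternative, 146 genes and 7 lists passed the threshold only in the alternative, and 272 and 31 lost it. Depth limits genes near the floor of the pax2a-low libraries.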

Other observations

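The ionocyte list, its depth test, the mitochondrial test on unscaled library sizes, the ratios to tg and the test on nuclear oxidative phosphorylation genes were chosen after the results were seen. Genes of ionocytes, the ion-transporting cells of fish skin and gill, were lower in the pax2a-high cells well beyond the fixed list. Of 33 tested members of the added list, 16 fell and 1 rose over all genes, and 19 were lower and 2 higher when adjusted over the list alone (median log2 fold change -6.47), but members were partly chosen for being lower, so no test of the list as a whole is given. Of the 16 tested members not seen before, 5 fell (camera p = 0.0047 with an estimated correlation). These 16 include 6 kcnj1a or atp1a1a copies of genes already seen. Of the other 10, 2 fell, and camera was not run on those 10 alone. The ionocyte factor genes foxi3b and dmrt2a had 4 and 2 counts over the pax2a-high libraries and 8573 and 7905 over the pax2a-low ones. The pump subunit gene atp1a1a.2 fell (log2 fold change -10.25, SE 1.41, edgeR adjusted p = 0.014; lost without pax2a-high replicate 3, pax2a-low replicate 1 or pax2a-low replicate 3, with 0.242, 0.149 and 0.141), as did the calcium exporter genes slc8a1b (-12.07, SE 1.43) and atp2b1a (-4.60, SE 0.84). With limma the atp1a1a.2 call was also lost (limma adjusted p = 0.283). The beta subunit gene atp1b1a went the other way from its copy atp1b1b and rose (3.77, SE 0.58, edgeR adjusted p = 0.0011), and the calls on slc8a1b, atp2b1a and atp1b1a were lost without both libraries numbered 1 (0.085, 0.153 and 0.244) or 2 (0.089, 0.156 and 0.056).

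A candidate explanation for the ionocyte genes is ionocytes among the pax2a-low cells. The 16 markers whose values had not been seen had a median log2 fold change of -2.77, below the bound of -1 set before, and the 10 that are not copies of seen genes had -1.94, with 8 negative and 2 past the threshold. Loss by sampling in the pax2a-high libraries, which are the deeper ones, is argued against by the 16 not seen before. Their median share of the predicted pax2a-high count was 0.1645 (95% interval 0.01533 to 0.6652), where sampling gives 1. The 16 include 6 copies of seen genes, and the share was not taken over the other 10 alone. The median of 0.01533 over all members is partly their selection. The pooled share of 0.2065 lay within the 10 times that this test had allowed for sampling, a bound set too loose. Of the 33 members, 12 had at least 5 CPM in pax2a-high cells and 7 stood on a list fixed before. A gate on the tg-driven EGFP would remove such cells, its use is not given in the sources used here, and ionocyte genes switched on in follicular cells stay open and untested.

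The high mitochondrial share of the pax2a-low libraries came with 13 of 13 mitochondrial genes past the threshold. Whether mitochondrial genes push the others down was not decided. On unscaled library sizes, leaving them out moved the genes past the threshold from 76 to 52 higher and from 172 to 333 lower. The change was up to 1.936 times, over the bound of 1.5. Leaving out rows of so unequal a share shifts every gene alike (median log2 fold change from 0.185 to -0.327), so this only restates the share. With TMM scaling, which already corrects for such rows, all 140 and 183 were still called without them. The calls reported here therefore did not rest on counting these rows in the library sizes. A mitochondrion-rich cell type cannot be told apart from other causes here: nuclear oxidative phosphorylation genes had a median log2 fold change of -0.917, but their camera adjusted p with an estimated correlation was 0.422. RNA quality and a difference in mitochondria between the sorted populations were not tested.

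For the lower thyroid genes of the pax2a-low cells, thinning left the median log2 fold change of the thyroid hormone genes tested at both depths at 2.9899 against 3.1641. The difference was still present at equal depth. Thinning keeps the scaled fold changes of well-counted genes near their value, so the predicted shrinkage could hardly occur and this test does not decide on depth. A single dilution of follicular cells by cells lacking thyroid transcripts would keep each gene's ratio to tg. Of 17 tested thyroid genes, 6 differed in that ratio over 2 times with no overlap. For no overlap alone, chance gives 10% per gene. All 17 ratios share tg as denominator, so they are not independent, and the share over all tested genes was not taken. In 5 of the 6 without overlap, dio3b, thrb, thraa, pax8 and prdm1a, the ratio was higher in pax2a-low. Transcripts of the added cells could give this, so the bound set for this test was wrong for such genes. The tg-driven EGFP also had a higher ratio, 7.81 ± 4.49 per 1000 tg counts against 1.55 ± 0.252 (SD, n = 3 each) with no overlap. This argues against added cells lacking both EGFP and tg as the only cause. Such cells leave the ratio unchanged, so it does not exclude them beside a lower tg output. Of the 6, only IYD had a lower ratio, from 6 pax2a-low counts. Dilution by cells holding EGFP, a lower output of the follicular cells, and a mix of these with cells lacking EGFP and tg therefore cannot be told apart. A difference between the populations, as the design names it, stays open.

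The 6 libraries can be split 3 against 3 in 10 ways, too few for a share under 0.05. The real split gave 323 genes past the threshold and the highest of the others 0, and 1 split, the real one, gave as many.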
